A study of Mus musculus with 4 samples.

How the data were processed

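Poly(A) RNA from mouse brain at embryonic day 13 was sequenced for 2 Wt1_flfl and 2 Wt1_CKO samples. Per the labels' protocols, RNA was enriched on oligo(dT) beads and copied with random primers, and the labels do not say whether the libraries kept strand. Per the submitters' processing notes the tools were Bowtie2 2.2.3, TopHat2 2.0.12 and HTSeq 0.6.0 and the build mm9. The positions in the deposited tables were checked against GENCODE vM21, which is on GRCm38. Of 22414 gene IDs, 22368 were found there, and 20606 of these (92.1%) had the same chromosome, start and end, so positions are given on GRCm38 as the tables give them.

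The authors deposited 1 table per pair of same-numbered samples. Per the file headers each holds whole-number counts per Ensembl gene for 2 libraries. The deposited CPM columns equal the count divided by a library total, with a count of 0 entered as 0.5 counts, and that total exceeded the listed counts by at most 0.0225%. The deposited fold ratio is the ratio of those CPM values and the deposited log2 column its logarithm. The authors' p-values and adjusted p-values compare 1 library with 1 library by a test not given in the sources used here. The authors' mark of significance fitted an adjusted p under 0.05 with an absolute log2 fold change of at least 1, for 674 genes of pair 1 and 666 of pair 2. Every listed gene had at least 2 counts over the 2 libraries, with 21047 and 20867 genes, 19500 in both tables, 1547 in the first only and 1367 in the second only. Wt1 is not reported here.

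The deposited counts of genes listed in both tables were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM, and a quasi-likelihood F test compared the genotypes with no other term, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values in the results are counts scaled to a TMM-adjusted library of 1000000, except that the summed CPM of Rpl3 and its copies, the CPM of regional and tissue markers and the comparison of the pairs used the listed library totals without TMM. Fold changes within a pair are differences of log2 CPM with a prior count of 2, and the SE of a log2 fold change comes from the SDs of the 2 groups on that scale. With n = 2 per group such an SE is itself imprecise and can fall below the counting error. It is not the spread that edgeR's test uses. A total of 38 gene lists was written before the data were examined. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at a preset correlation of 0.01. Terms of the deposited biological process column with 10 to 500 tested genes were tested with Fisher's exact test, one-sided, on the 200 genes with the smallest p-values per direction, as too few genes passed the threshold, against 12879 tested genes with a term. The pairs were compared on log2 of CPM plus 1, with intervals from 1000 bootstrap draws of genes.

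The named genes were chosen by a rule fixed before the data were examined. It took Wt1, then up to 10 genes per direction past the threshold with a mean of at least 1 CPM and the same direction in both pairs, filled to 10 by the smallest unadjusted p among genes with the same direction in both pairs. It added up to 4 members of each list by the smallest p, and Epo, Epor, Tet2, Nes, Sox2, Pax6, Eomes, Tubb3 and Mki67. Genes named outside it were chosen after their values were seen.

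The test was tried on simulated counts drawn from the means and library sizes of these samples, with 15643 genes tested. It recovered 55.8% of 95 genes changed by a log2 fold of 1 and 93.8% of 96 genes changed by 2, and called 10 unchanged genes. A list moved in the simulation was called and no unchanged list was. The simulated counts followed the dispersion trend, with no gene-specific dispersion, no difference by replicate number and no correlation between genes. The recovered shares are therefore not the power of the test on the real samples. The list result does not check the preset correlation. The samples held 16219310 to 17704698 counts each, and the common biological coefficient of variation was 0.171. Reads without molecular identifiers are not independent molecules, so the Wilson intervals on shares of counts cover counting error only.

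The alternatives were the replicate number as a block, leaving out each library, DESeq2 size factors, no low-count filter and a stricter one, DESeq2 1.42.0, limma-voom, robust edgeR, and leaving out haemoglobin, mitochondrial and sex-linked genes. For the lists they were an estimated correlation and fry, for the pairs other pseudocounts (0.1 and 5), a crossed pairing and genes of at least 10 CPM, and for the authors' marks an adjusted p under 0.01. Tests on genes of either table with a missing gene entered as 0, on protein-coding genes only, and on 100 or 400 genes per direction for terms were added after the data were seen. Pseudocount and quantile alternatives for normalized values were not run, as counts were used, and the alternative log2 threshold for the authors' marks is already part of them. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1 were used for the rest.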

Results

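RNA-seq was performed on mouse brain at embryonic day 13, from animals with floxed Wt1 alleles (Wt1 fl/fl, called Wt1_flfl) and from animals labelled as a Wt1 conditional knockout (Wt1_CKO), on a C57BL/6 background. Wt1 encodes a zinc finger transcription factor, and the study asked how it acts on the proliferation and differentiation of neural progenitors. Each genotype had 2 samples, numbered 1 and 2, and the deposited tables each held the 2 samples of one number, called pair 1 and pair 2 here. The tables listed 16219310 counts for Wt1_flfl replicate 1, 17170578 for Wt1_flfl replicate 2, 17704698 for Wt1_CKO replicate 1 and 17159450 for Wt1_CKO replicate 2. No label says whether the samples came from separate animals or pools, so the p-values measure only the spread between these samples. The labels do not name the Cre line or the part of the brain that was taken.

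The Wt1 transcript was not analysed here, so the genotype labels were not checked against the targeted gene. Erythropoietin and its receptor were fixed for report as genes tied to Wt1 in other work. Epo had 6 counts in Wt1_flfl replicate 1 and 0 counts in Wt1_CKO replicate 1, too few for a fold, and was not analysed here in pair 2. Epor had 1.81 ± 0.0813 CPM (counts scaled to a library of 1000000; SD, n = 2) in Wt1_flfl and 2.54 ± 0.0627 CPM (SD, n = 2) in Wt1_CKO brain. Its log2 fold change of 0.49 with an SE of 0.0493 did not pass edgeR's quasi-likelihood test. That SE comes only from the spread of n = 2 samples per group, and at so few CPM counting error alone may exceed it.

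The first comparison asked which transcripts differed between Wt1_CKO and Wt1_flfl brain. Of 15933 genes tested, 1 passed a Benjamini-Hochberg adjusted p of 0.05, the processed pseudogene Rpl3-ps1, which was lower in Wt1_CKO. Rpl3-ps1 (ENSMUSG00000084349, chromosome X, 13202571 to 13203780, GRCm38) fell from 168 ± 23.9 CPM (SD, n = 2) in Wt1_flfl to 33.3 ± 0.325 CPM (SD, n = 2) in Wt1_CKO. Its log2 fold change was -2.33 with an SE of 0.146, and edgeR's adjusted p was 0.0162. The fold change was -2.46 in pair 1 and -2.19 in pair 2. This pseudogene is annotated as a processed copy of Rpl3, which encodes a protein of the large ribosomal subunit, and reads can be split between the copies, so the value is uncertain. Rpl3 itself (chromosome 15, 80077794 to 80091868) had 608 ± 94.6 CPM (SD, n = 2) in Wt1_flfl and 833 ± 5.32 CPM (SD, n = 2) in Wt1_CKO. The summed CPM of Rpl3, Rpl3-ps1 and Rpl3-ps2 was 855 in Wt1_flfl replicate 1, 874 in Wt1_CKO replicate 1, 692 in Wt1_flfl replicate 2 and 866 in Wt1_CKO replicate 2. An unadjusted edgeR p under 0.05 was found for 249 genes, 95 higher and 154 lower in Wt1_CKO. Apart from Rpl3-ps1 these genes did not pass after adjustment, so they cannot be read as changed genes. They are a share of the 15933 genes under 0.05. The libraries also separated by replicate number, and that difference stays in the spread of this test and may lower the share. The low share therefore does not show that no other gene changed. The count of adjusted calls depended on single libraries. It was 73 without Wt1_flfl replicate 1, 29 without Wt1_flfl replicate 2, 3 without Wt1_CKO replicate 1 and 7 without Wt1_CKO replicate 2, and DESeq2 called 5.

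None of the 9 further genes ranked lowest in Wt1_CKO by unadjusted p passed edgeR's test with genotype as its only term. Olig3 (ENSMUSG00000045591, chromosome 10, 19356533 to 19358604), a bHLH factor of the embryonic thalamus, had 10.3 ± 1.53 CPM (SD, n = 2) in Wt1_flfl and 1.11 ± 0.0956 CPM (SD, n = 2) in Wt1_CKO. Its log2 fold change was -3.19 with an SE of 0.170, and its edgeR adjusted p of 0.118 missed the threshold. Olig3 passed in each of the 4 edgeR fits without 1 library and with DESeq2, and its adjusted p over the alternatives ran from 6.71e-10 to 0.408. Shox2 (ENSMUSG00000027833, chromosome 3, 66971727 to 66981771), a homeobox gene of the habenula and thalamus, had 6.49 ± 2.89 CPM in Wt1_flfl and 0.396 ± 0.314 CPM in Wt1_CKO (SD, n = 2 each). Its libraries held 137 and 76 counts against 11 and 3. Tcf7l2 (ENSMUSG00000024985, chromosome 19, 55741810 to 55933654), a Wnt pathway factor abundant in the thalamus, had 54.4 ± 14.9 CPM in Wt1_flfl and 21.0 ± 3.59 CPM in Wt1_CKO (SD, n = 2 each), with a log2 fold change of -1.37 and an SE of 0.333. Shox2 and Tcf7l2 passed with DESeq2 and in the edgeR fits without Wt1_flfl replicate 1 or without Wt1_flfl replicate 2, and missed without either Wt1_CKO library. The forkhead gene Foxa1 had 20 and 35 counts in the Wt1_flfl libraries and 3 and 0 counts in the Wt1_CKO libraries. The Wnt receptor Fzd10 had a log2 fold change of -1.70 (SE 0.211), the chloride cotransporter Slc12a2 one of -0.59 (SE 0.131) and Zic2 one of -0.56 (SE 0.120). The remaining ranked genes were the pseudogenes Rpl3-ps2 and Gm14584, whose reads can also be shared with other genes. Each of these genes was lower in Wt1_CKO in both pairs, which the ranking rule required.

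None of the 10 genes ranked highest in Wt1_CKO passed the same test. Slc15a2 (ENSMUSG00000022899, chromosome 16, 36750178 to 36784962), a peptide transporter, had 21.9 ± 6.95 CPM in Wt1_flfl and 54.7 ± 8.68 CPM in Wt1_CKO (SD, n = 2 each). Its log2 fold change was 1.32 with an SE of 0.365. It passed with DESeq2 and without Wt1_flfl replicate 1 or Wt1_flfl replicate 2, and missed without either Wt1_CKO library. Gli3, a transcription factor of Hedgehog signalling in the dorsal forebrain, had 78.0 ± 1.84 CPM in Wt1_flfl and 98.7 ± 2.31 CPM in Wt1_CKO (SD, n = 2 each). The log2 fold changes were 0.63 (SE 0.0461) for Pot1b, a telomere protein, 0.63 (SE 0.118) for the DNA damage kinase Atm and 0.73 (SE 0.162) for the splicing factor Rbm20. The others were Rpl3, Mid1-ps1, Gm9800, Gm37447 and Gm43012. Gm43012 held 1 and 3 counts in Wt1_flfl and 14 and 16 in Wt1_CKO. Mid1-ps1 and Gm9800 are pseudogenes and uncertain for the same reason as Rpl3-ps1. Mid1-ps1 lies on the Y chromosome in the annotation, yet it had 26 counts in Wt1_flfl replicate 2 and 131 in Wt1_CKO replicate 2, libraries with 16129 and 16472 counts of Xist, the X-inactivation RNA of females.

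**Figure D1:**
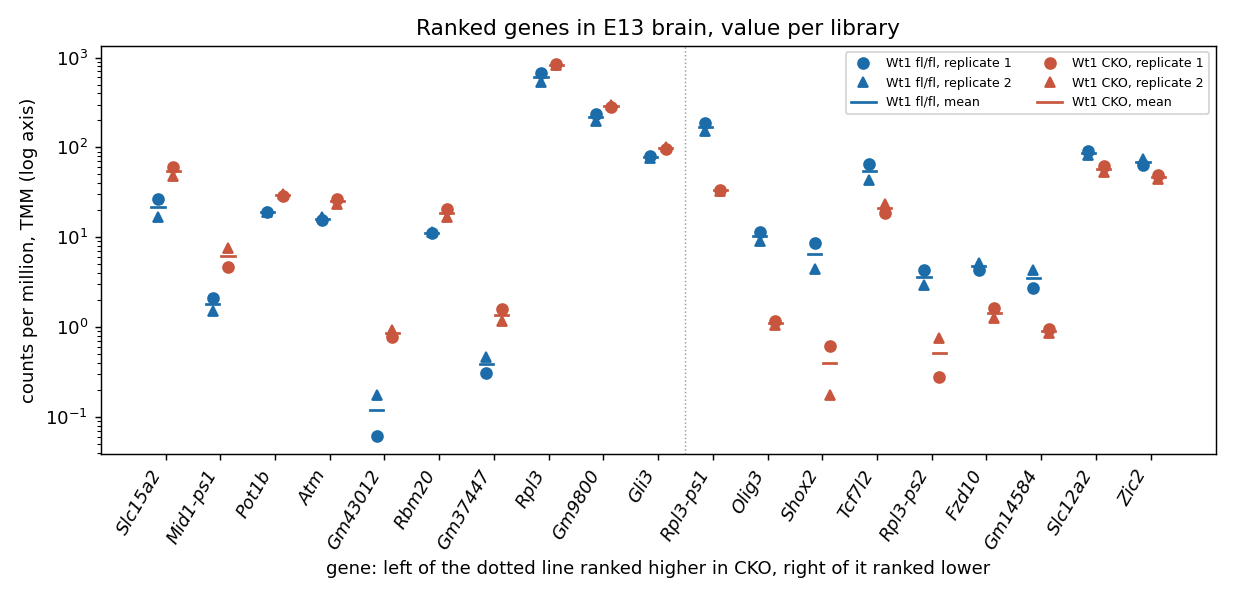
CPM (TMM-scaled, log axis) of the ranked genes that had counts in all libraries, with circles for replicates 1, triangles for replicates 2 and short lines for group means. Rpl3-ps1 alone passed the adjusted threshold, with means of 168 CPM in Wt1_flfl and 33.3 CPM in Wt1_CKO.

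The study's subject is progenitor proliferation and differentiation, and lists of progenitor, neuronal and cell cycle genes were compared. The lists of S phase and of G2 and M phase genes were higher in Wt1_CKO with camera at a preset correlation, with adjusted p of 0.0157 and 0.0089. Their adjusted p was 0.959 for each with an estimated correlation, a setting that could hardly call any list with so few libraries. Of 25 G2 and M phase genes, 17 were higher in both pairs and 0 lower in both, and the median log2 fold change was 0.14. Ccnb1, the mitotic cyclin, had 169 ± 4.49 CPM in Wt1_flfl and 204 ± 2.01 CPM in Wt1_CKO (SD, n = 2 each), and Bub1b, of the spindle checkpoint, had 106 ± 5.93 and 126 ± 2.74 CPM. Of 25 S phase genes, 13 were higher in both pairs and 1 lower in both, with a median of 0.12. Within pairs the S phase median was 0.01 in pair 1 and 0.17 in pair 2. The list of replication-dependent histones, with 4 of 19 genes tested, had a median of -0.69, and -0.86 and 0.09 in pairs 1 and 2. Histone transcripts summed to 301 CPM without TMM in Wt1_flfl replicate 1, against 191 CPM in Wt1_CKO replicate 1. They summed to 189 CPM in Wt1_flfl replicate 2 and 213 CPM in Wt1_CKO replicate 2. Wt1_flfl replicate 1 also stood apart in RNAs that usually lack a poly(A) tail, so the histone median of pair 1 is not read as a cell cycle result. Pola1, the catalytic subunit of DNA polymerase alpha, had 33.8 ± 1.77 CPM in Wt1_flfl and 43.2 ± 2.64 CPM in Wt1_CKO (SD, n = 2 each). No member of either list passed, over all genes or adjusted over the list alone. The G2 and M phase adjusted p was 0.53 without Wt1_flfl replicate 2 and 0.22 without Wt1_CKO replicate 2. The S phase adjusted p was 0.333 and 0.514 without the same libraries and 0.0745 without Wt1_flfl replicate 1.

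None of the progenitor and neuron markers fixed for report passed edgeR's test. The proliferation marker Mki67 had 364 ± 10.6 CPM in Wt1_flfl and 420 ± 53.9 CPM in Wt1_CKO (SD, n = 2 each). Nes, an intermediate filament of neural stem cells, had 624 ± 223 and 669 ± 210 CPM. Sox2 had 327 ± 29.1 and 294 ± 47.5 CPM, Pax6 119 ± 5.02 and 129 ± 3.94 CPM, and Eomes, of intermediate progenitors, 134 ± 27.5 and 160 ± 27.6 CPM. Tubb3, a neuronal tubulin, had 2292 ± 122 and 2018 ± 47.6 CPM, and the methylcytosine oxidase gene Tet2 had 40.7 ± 4.10 and 42.6 ± 7.20 CPM. In each of these pairs of values Wt1_flfl is given first, with the SD over n = 2, and edgeR's adjusted p was 1 for each gene. The direction for Nes and Tet2 turned without Wt1_flfl replicate 1 and without Wt1_CKO replicate 2. Camera called neither the neural stem and radial glial list (adjusted p 0.293), nor the intermediate progenitor list (0.908), nor the postmitotic neuron list (0.475).

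Lists of cells from outside the dorsal cortex were lower in Wt1_CKO with the preset correlation. The list of GABAergic and ventral telencephalic cells had a camera adjusted p of 0.00478, and an adjusted p of 0.98 with an estimated correlation. Of its 18 members, 15 were lower in both pairs and 0 higher in both, with a median log2 fold change of -0.23. Isl1 had 93.0 ± 11.6 CPM in Wt1_flfl and 70.9 ± 15.6 CPM in Wt1_CKO (SD, n = 2 each). No member passed. Without Wt1_CKO replicate 1 this list turned direction, with an adjusted p of 0.888, and without Wt1_flfl replicate 2 its adjusted p was 0.53.

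The list of glutamatergic neurons outside the cortex had a camera adjusted p of 0.0041, and an adjusted p of 0.959 with an estimated correlation. Of its 10 tested members 5 were lower in both pairs and 1 higher in both. No member passed over all genes, and 2 passed when adjusted over the list alone, Shox2 and Tcf7l2, with adjusted p of 0.0028 each. Lhx5 had 34.5 ± 17.8 CPM in Wt1_flfl and 19.6 ± 1.49 CPM in Wt1_CKO (SD, n = 2 each). The adjusted p of this list was 0.0603 without Wt1_flfl replicate 2. The list of regional patterning genes had a camera adjusted p of 0.0156, and an adjusted p of 0.959 with an estimated correlation. Only 8 of its 23 genes were tested, of which 4 were lower in both pairs, and none passed. Irx1 had 14 and 17 counts in Wt1_flfl and 4 and 6 in Wt1_CKO, and Otx2 had 26.9 ± 6.34 CPM in Wt1_flfl and 19.9 ± 5.79 CPM in Wt1_CKO (SD, n = 2 each). Gbx2 had a log2 fold change of -1.47 in pair 1 and 0.01 in pair 2. The adjusted p of this list was 0.0681 without Wt1_CKO replicate 1 and 0.265 without Wt1_flfl replicate 1.

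Of the 34 lists with at least 5 tested members, camera called those 5 with the preset correlation and 8 at an unadjusted p under 0.05. With an estimated correlation camera called 0, with 0 at an unadjusted p under 0.05, and fry called 0, with 3. Of these 34 lists, camera at the preset correlation called 8 without Wt1_flfl replicate 1, 8 without Wt1_CKO replicate 1, 1 without Wt1_flfl replicate 2 and 4 without Wt1_CKO replicate 2. In the Hedgehog list 1 of 14 tested members, Foxa1, passed when adjusted over the list alone, with an adjusted p of 0.0358, and none passed over all genes. Apart from Shox2, Tcf7l2 and Foxa1, no list member passed either threshold. Among lists not called, the median, the mean and camera's direction differed in sign for postmitotic neurons, cell cycle inhibitors, BMP and TGF beta signalling, DNA methylation machinery, astrocyte and oligodendrocyte lineage, neural crest, erythroid cells, microglia, choroid plexus and the eye list, which had too few members for camera. Some lists of other tissues that a dissected brain may hold moved apart between the pairs. The median log2 fold change of the choroid plexus list was 0.33 in pair 1 and -0.53 in pair 2, that of the erythroid list -0.58 and 0.18, and that of the meninges and mesenchyme list 0.00 and -0.75. Others moved the same way in both pairs, with medians of -0.18 and -0.04 for endothelial cells, -0.22 and -0.56 for surface epithelium and -0.15 and -0.07 for cartilage and bone. No biological process term passed among the 200 genes with the smallest p-values in either direction by Fisher's exact test. Of 1881 terms, 62 for the higher and 80 for the lower genes had an unadjusted p under 0.05. Each is a share under 0.05. With few genes expected per term the p-values move in coarse steps, so unrelated genes need not give a share of 0.05. The share they would give was not computed, and no conclusion is drawn from these numbers. The lowest adjusted p was 0.296 for DNA replication among the higher genes, where 7 genes stood against 1.16 expected, and 0.326 for metanephros development among the lower genes.

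**Figure D2:**
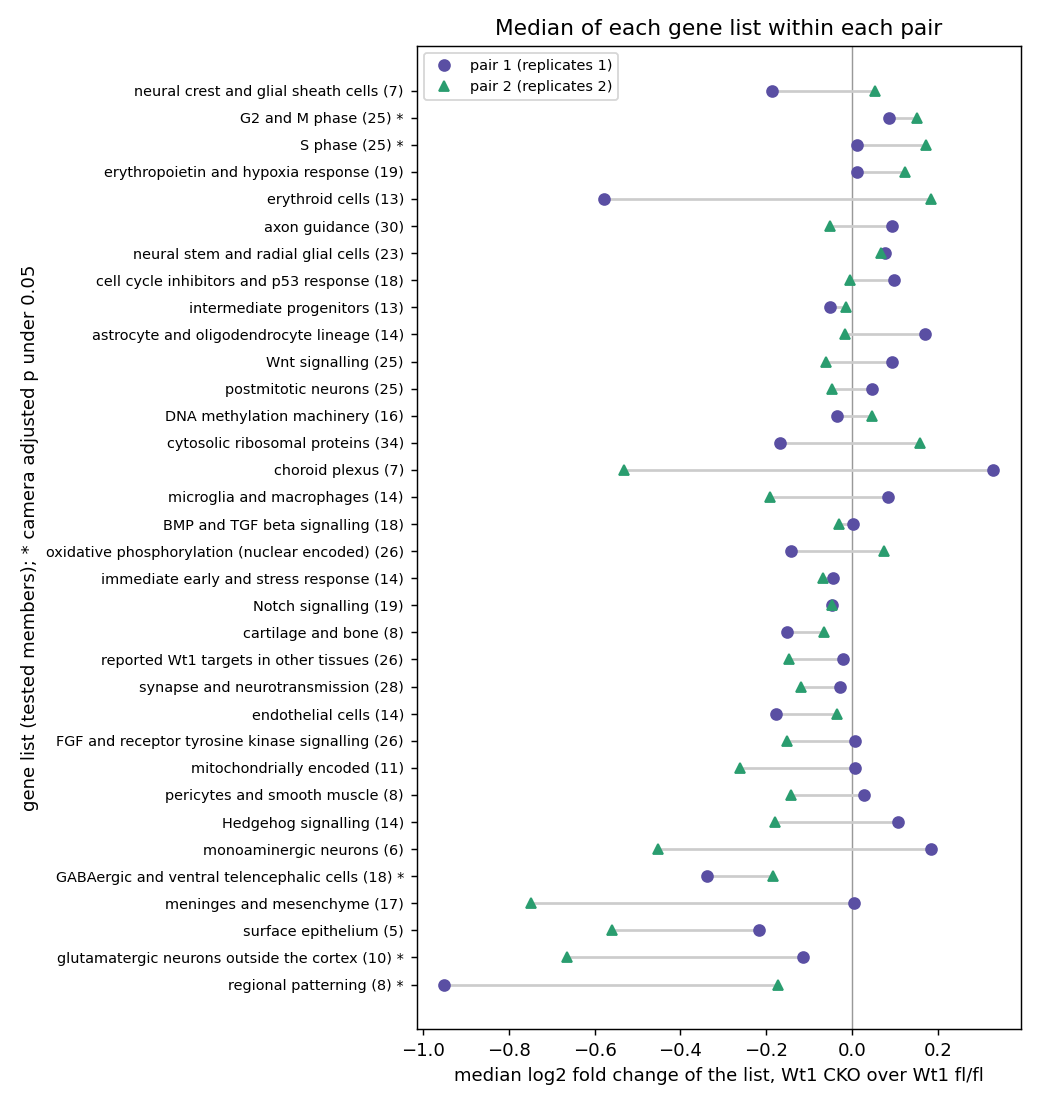
Median log2 fold change, Wt1_CKO over Wt1_flfl, of the tested members of each of 34 gene lists within pair 1 (circles) and pair 2 (triangles), with a grey line joining the 2 medians. The 5 lists that camera called with the preset correlation are starred, and the choroid plexus list lies at 0.33 in pair 1 and -0.53 in pair 2.

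The deposited tables set same-numbered samples side by side, though no label links them, and the fold changes of the 2 tables were compared. Across 15933 genes the log2 fold changes of pair 1 and pair 2 had a Pearson correlation of -0.03, with a 95% bootstrap interval over genes from -0.07 to 0.01, and a Spearman correlation of 0.06. These are across genes, which are not independent replicates. The 2 pairs had the same direction for 53.3% of genes, and for 55.3% of the 10135 genes with a mean of at least 10 CPM.

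The authors' deposited tables give their own calls for each pair, which compare 1 library with 1 library and not the genotypes. The authors' deposited table for pair 1 marks 352 genes as higher and 322 as lower in Wt1_CKO, and that for pair 2 marks 264 and 402. Of 19500 genes listed in both, the authors' deposited tables mark 29 the same way in both pairs, 10 higher and 19 lower. Among those genes, the tables mark 328 and 243 as higher and 270 and 366 as lower, and independent lists of these sizes would share 4.09 and 5.07. Slc15a2, Olig3, Shox2, Foxa1, Fzd10, Irx3 and Rpl3-ps1 are among these 29 in the authors' deposited tables. The authors' deposited tables mark 60 genes in opposite directions, where independent lists would share 9.52. Of these, 37 are higher in pair 1 and lower in pair 2, such as the choroid plexus gene Ttr with 4 counts in Wt1_flfl replicate 1, 717 in Wt1_CKO replicate 1, 213 in Wt1_flfl replicate 2 and 17 in Wt1_CKO replicate 2. The other 23 are lower in pair 1 and higher in pair 2, such as the nuclear receptor gene Nr1h5 with 167, 2, 1 and 143 counts in the same order. Ttr and Nr1h5 were chosen after their values were seen.

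**Figure D3:**
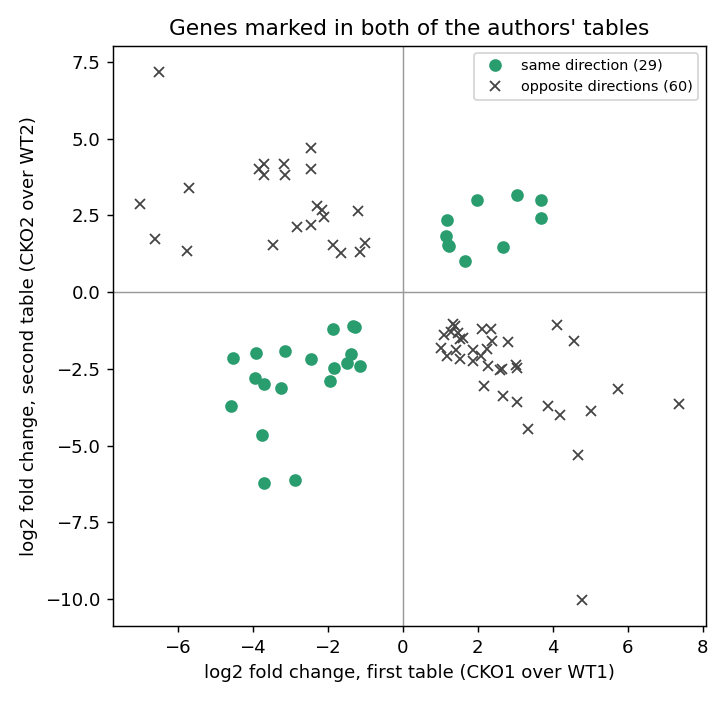
Log2 fold changes from the authors' deposited tables for the 89 genes marked in both, with pair 1 on the horizontal and pair 2 on the vertical axis. The 29 genes marked the same way (circles) lie in the lower left and upper right, and the 60 marked in opposite ways (crosses) lie in the other corners.

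The libraries differed in ways that the genotype does not describe. Xist had 13086 counts in Wt1_flfl replicate 1, 16129 in Wt1_flfl replicate 2, 16472 in Wt1_CKO replicate 2 and 4 in Wt1_CKO replicate 1. The Y-linked genes, Ddx3y, Eif2s3y, Kdm5d and Uty, together had 4275 counts in Wt1_CKO replicate 1 and 4 in Wt1_flfl replicate 1, and were not analysed here in pair 2. Globin transcripts took 0.0948% of the counts of Wt1_flfl replicate 1 (95% Wilson interval 0.0933 to 0.0963) and 0.0907% of Wt1_CKO replicate 1 (0.0893 to 0.0921). They took 0.181% of Wt1_flfl replicate 2 (0.179 to 0.183) and 0.177% of Wt1_CKO replicate 2 (0.175 to 0.179). Ribosomal RNA took 0.63% of the counts of Wt1_flfl replicate 1 (0.626 to 0.634), and the highest share among the others was 0.127% in Wt1_CKO replicate 1 (0.125 to 0.129). The first principal component held 49.97% of the variance and separated the replicate numbers. The second held 27.5% and separated the crossed split, and the third held 22.55% and separated the genotypes.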

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

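Genes listed in 1 of the 2 tables did not enter the genotype test. Among them, 6 had at least 50 counts in a Wt1_CKO library and at least 10 times the Wt1_flfl count of the same pair, all in Wt1_CKO replicate 1. They were Eif2s3y with 1776 counts against 4, Kdm5d with 1141 against 0, Ddx3y with 846 against 0, Uty with 512 against 0, the Y-linked Gm29650 with 272 against 2, and Zfp984 on chromosome 4 with 80 against 0. By the same bounds 5 genes had more counts in Wt1_flfl. In pair 2 they were Six6 with 131 counts in Wt1_flfl against 1 in Wt1_CKO, Apob with 69 against 0, Nkx2-4 with 69 against 0 and Gm4881 with 64 against 1, and in pair 1 Hist1h1b with 61 against 1. These are counts of 1 library against 1 library, and no test was made.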

How the results depend on the processing

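The genes of either table, protein-coding genes only, and 100 or 400 genes per direction for terms were alternatives added after seeing the data. Rpl3-ps1 kept its direction and its call in the 13 alternatives that tested it, with log2 fold changes from -2.47 to -2.18 and adjusted p from 2.14e-39 to 0.0249. The count of called genes, 1 as reported (0 higher, 1 lower), was 5 with DESeq2 (1 higher, 4 lower) and 0 among protein-coding genes, where edgeR gave 202 genes at an unadjusted p under 0.05. Without 1 library at a time it ranged from 3 to 73 (0 to 11 higher, 3 to 62 lower), and the cause was not tested. The remaining alternatives without the block gave 1. With the replicate number as a replicate block it was 42 (8 higher, 34 lower), among them the 10 genes ranked lower, Slc15a2 and Mid1-ps1, all ranked on the same direction in both pairs. Same-numbered samples share a number and a deposited table, with 2 pairs and no label that links them otherwise. Their deviations correlated at 0.28 across genes, and the split by replicate number called 313 genes. The fit without the block keeps this difference in its spread, which may lower its count of calls. At an unadjusted p under 0.05 edgeR gave 1146 genes with the block and 249 without it. Whether the samples were paired cannot be told from the labels. The 5 called lists became 0 with an estimated correlation and 0 with fry, and 2 to 10 without 1 library, where 35 or 36 lists had enough tested members (1 to 8 among the 34 reported). With the block camera called 7 lists, as meninges and mesenchyme (adjusted p 0.0461) and surface epithelium (0.0213) were added, each at 0.0506 as reported. With no low-count filter it called 7 of 36 lists, 5 of them among the 34 reported. The correlation between pairs was 0.00994 with a pseudocount of 5 and -0.40 with the crossed pairing. In the crossed pairing the difference by replicate number enters the 2 fold changes with opposite signs, which pushes their correlation down. That value is therefore not read as a result about genotype or exchanged labels. At an adjusted p under 0.01 the authors' tables marked 13 genes the same way and 34 in opposite ways. No term was called with 100, 200 or 400 genes.

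Among named genes, the log2 fold change of Tet2 ranged from -0.12 to 0.23 and that of Nes from -0.26 to 0.52 without 1 library, and the other named genes kept their direction in the alternatives that tested them. Lists that reversed had these adjusted p in the fits without 1 library: cell cycle inhibitors 0.722 to 0.970, Wnt 0.073 to 0.710, BMP and TGF beta 0.535 to 0.888, astrocyte and oligodendrocyte 0.543 to 0.985, neural crest 0.218 to 0.957, pericytes 0.206 to 0.888, choroid plexus 0.0961 to 0.588, intermediate progenitors 0.483 to 0.888, postmitotic neurons 0.0245 to 0.932, GABAergic 9.63e-07 to 0.888, Notch 0.198 to 0.888, Hedgehog 0.135 to 0.888, Wt1 targets 0.0719 to 0.843, erythropoietin and hypoxia 0.0379 to 0.722, DNA methylation 0.12 to 0.722, axon guidance 0.373 to 0.942, synapse 0.0075 to 0.959, monoaminergic 0.0363 to 0.873, erythroid 0.0022 to 0.530, meninges 0.00064 to 0.722, microglia 0.357 to 0.985, surface epithelium 0.0165 to 0.722, cartilage and bone 0.225 to 0.888, mitochondrially encoded 0.0075 to 0.535, ribosomal proteins 0.0262 to 0.447, and oxidative phosphorylation 0.158 to 0.847. Other reversals were cell cycle inhibitors (0.957) and astrocyte and oligodendrocyte (0.802) with the block, BMP and TGF beta (0.925), neural crest (0.954) and choroid plexus (0.882) with no low-count filter, and Wnt, pericytes and choroid plexus with fry (0.976 each). The cause was not tested. With 1 sample left in a group, that sample is assumed to vary like the other group. Genes with few counts, such as Foxa1 and Gm43012, are limited by depth.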

Other observations

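The tests of explanations in this part were all chosen after the results they bear on had been seen, and those of tissue share, sex, exchanged labels and developmental age replaced earlier versions whose outcome had been seen. The marker lists of brain regions and globins were written after the ranked genes were seen, and the genes named here from outside the naming rule were chosen after their values were seen.

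Of 8 midbrain markers 5 were analysed and 1 was tested, and over these 5 the libraries had 2.22 CPM in Wt1_flfl replicate 1, 1.81 CPM in Wt1_CKO replicate 1, 6.06 CPM in Wt1_flfl replicate 2 and 1.22 CPM in Wt1_CKO replicate 2, most of it from Tal2 and Lmx1b. Of 6 hindbrain markers 1 was analysed here, Egr2, with 1 count in each library of pair 1. Hypothalamic markers summed to 144 CPM in Wt1_flfl replicate 2 and to 10.97, 17.7 and 23.6 CPM in Wt1_flfl replicate 1, Wt1_CKO replicate 1 and Wt1_CKO replicate 2. Otp had 1438 counts in Wt1_flfl replicate 2 and 96, 204 and 279 in the others, and Nr5a1 had 150 against 1, 2 and 0.

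Wt1_flfl replicate 1 stood apart in RNAs that usually lack a poly(A) tail. Rn7sk had 1201 counts there and 23, 14 and 25 in Wt1_CKO replicate 1, Wt1_flfl replicate 2 and Wt1_CKO replicate 2, and Rpph1 had 346 against 12, 3 and 9. Histone transcripts, Hist1h1b among them, were also highest there, with 301 CPM without TMM against 191, 189 and 213 CPM in the same order.

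The 3 lists of GABAergic and ventral cells, glutamatergic neurons outside the cortex and regional patterning were called lower in Wt1_CKO with camera's preset correlation. With an estimated correlation their adjusted p was 0.98, 0.959 and 0.959, and none was called, though that setting could hardly call any list here. Over their 36 tested members the median log2 fold change was -0.34 in pair 1 and -0.21 in pair 2, with 24 lower in both. The difference in sex between the libraries of pair 1 stays open for pair 1 only. Both libraries of pair 2 had high Xist counts, 16129 in Wt1_flfl and 16472 in Wt1_CKO, and 27 of the 36 members were lower there. Those values, 1 library against 1 library, argue against sex as the source in pair 2. Leaving out Wt1_CKO replicate 1 also unbalances the replicate numbers, so that fit cannot separate sex from number. Without Wt1_CKO replicate 1, the library with Y-linked counts, 1 of the 3 lists was still called lower, that of glutamatergic neurons (adjusted p 0.0075), while the GABAergic list turned direction (0.888) and regional patterning lost its call (0.0681). Over the camera and fry alternatives that kept every library, the adjusted p of the glutamatergic list ran from 0.00427 to 0.959. It ran from 2.08e-05 to 0.98 for the GABAergic list and from 0.0127 to 0.976 for regional patterning. A smaller share of tissue from outside the cortex in both Wt1_CKO samples may contribute and was not settled. The 5 thalamic and habenular markers outside the 3 lists had medians of -0.11 in pair 1 and -0.53 in pair 2, with members going both ways. The 6 tested hypothalamic markers run against a loss in both pairs, with medians of 0.76 in pair 1 and -2.26 in pair 2, where Wt1_flfl replicate 2 stood apart. The 7 telencephalic markers outside the 3 lists had medians of 0.15 in pair 1 and 0.17 in pair 2, with 6 above 0 in each pair, the direction that a smaller share would give. Genotype itself stays open and untested as a cause.

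Genes that the authors' tables mark in opposite directions numbered 60. Choroid plexus and meningeal tissue carried into Wt1_CKO replicate 1 and Wt1_flfl replicate 2 is a candidate source for part of them, as Ttr and Clic6 were high in those libraries. Of the 37 genes higher in pair 1 and lower in pair 2, 4 belonged to the lists of these tissues. Those lists hold only 34 genes, against 19500 genes compared, so this count does not weigh against that source and does not settle it. The choroid plexus markers summed to 75.2 and 61.1 CPM in Wt1_CKO replicate 1 and Wt1_flfl replicate 2. They summed to 34.5 and 37.4 CPM in Wt1_flfl replicate 1 and Wt1_CKO replicate 2. To these sums Ttr gave 40.5, 12.4, 0.247 and 0.991 CPM in the same order. Otx2, which the regional patterning list also holds, gave 15.9, 31.3, 22.2 and 24.1 CPM. Afp, among the 37 and in neither list, had 1042 counts in Wt1_flfl replicate 2. It had 0, 15 and 1 in Wt1_flfl replicate 1, Wt1_CKO replicate 1 and Wt1_CKO replicate 2. Wt1_flfl replicate 2 also held 19 counts of Fga and 13 of Alb, against 0 of each in Wt1_CKO replicate 2. A further tissue in Wt1_flfl replicate 2 was not tested. Exchanged labels in one pair could also turn shared marks into opposite ones, and the correlation of -0.0301 across genes between the pairs' fold changes left this open, as no readout of the genotype was analysed here. Genes marked the same way, 29 where independent lists would share 9.16, and in opposite ways, 60 against 9.52, both exceeded those numbers, and the crossed split, which an exchange would give, called 4 genes against 1 by genotype. None of these decides it. No biological explanation was tested.

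Splitting the 4 libraries by replicate number gave 313 genes with edgeR, against 1 by genotype and 4 by the crossed split, which points to a structure of the samples. Replicates 2 had more of the embryonic globin Hbb-y, with 14528 and 16768 counts against 6797 and 6402, and more Ccnd1. A difference in developmental age may be behind it: the embryonic share of globin counts was 63.7% in Wt1_flfl replicate 2 (95% Wilson interval 63.1 to 64.2) and 76.8% in Wt1_CKO replicate 2 (76.3 to 77.2), against 52.9% (52.1 to 53.7) and 45.3% (44.5 to 46.1) in Wt1_flfl and Wt1_CKO replicates 1, and the postmitotic neuron list was lower in replicates 2, with medians of -0.17 in Wt1_flfl and -0.33 in Wt1_CKO. With an estimated correlation, which could hardly call any list here, the postmitotic neuron list was not called (adjusted p 0.74). The list of GABAergic and ventral cells went the other way, with medians of 0.34 and 0.51 (estimated correlation, adjusted p 0.74), and the neural stem list did not follow in both genotypes, with medians of -0.04 and 0.11. Age was therefore not settled. A difference in library preparation or alignment was not settled. Genes other than protein-coding made up 16.3% of the 313 and 14.3% of tested genes, a ratio of 1.14 (Fisher's exact p 0.327). That share cannot show jumps of single genes. The pseudogene Gm13394, with the smallest p, had 7335 and 7356 counts in Wt1_flfl and Wt1_CKO replicates 1, against 82 and 65 in replicates 2. In the same order Rps18 had 3439 and 3423 against 793 and 893, and the snoRNA Gm24598 141 and 157 against 1 and 1. Of the 313 genes, 172 were lower and 141 higher in replicates 2. The source of these jumps was not tested.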
